A study of Rattus norvegicus with 9 samples.

How the data were processed

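RNA sequencing of polyadenylated RNA was available for 9 kidneys of SD (Sprague-Dawley, an outbred laboratory stock) rats. The sample titles divided them into 3 groups of 3: control kidneys, kidneys of a chronic kidney disease (CKD) model, and kidneys treated with mesenchymal stem cells (MSCs, multipotent stromal cells used in cell therapy). How the disease was induced, the source and dose of the cells and the time of sampling were not given in the sources used here. The series title names an ultrasound-guided infusion into the renal parenchyma of a CKD rat model. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these libraries, which may in part be technical.

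Per the labels' protocols, RNA was extracted with TRIzol, polyadenylated RNA was captured on oligo(dT) beads, and a strand-specific library was made after fragmentation, reverse transcription and digestion with UDG. The submitters' processing notes name cutadapt, HISAT2 and StringTie, without versions, and the rat genome build Rnor_6.0. The annotation release, the strand setting of the counting and the filters were not given in the sources used here.

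The authors deposited 1 table of counts: whole-number, unscaled counts for 22637 Ensembl rat gene identifiers in 9 columns. Each column name matched the description of 1 sample. No row was 0 in all 9 libraries, so genes without any count were absent from the deposited table. The table held identifiers only. The gene table available for naming listed 47357 rat genes, of which 0 had an Ensembl identifier, so 0 of the 22637 identifiers could be paired with a symbol. Gene names, gene positions, gene length and GC content were therefore not used here. For the same reason the 36 gene lists fixed before the data were examined (among them fibrosis, tubular injury, nephron segment and immune cell markers) and the shares of mitochondrial and ribosomal protein genes were not computed, and no known disease gene could be checked against the labels. The rule for naming genes lost its condition on a symbol and was cut short, so only 4 identifiers are printed. They are the 2 with the largest positive and the 2 with the largest negative log2 fold between MSC and CKD kidneys. All 4 came from genes with adjusted p under 0.05, average log2 CPM of at least 1 and no overlap between both groups' values. The planned rule named more genes, also for CKD against control and MSC against control, and these are not printed.

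Total counts per library ranged from 47633344 to 58546847. At this depth counting error is small for all but the lowest genes. A count of 0 in a library allows up to 3 counts, which corresponds to 0.0478 to 0.0626 CPM (counts scaled to a common library total) in these libraries. That limit takes each count as an independent read and covers counting error only. Even and odd small values were unevenly frequent, without 1 direction. The values 1 to 6 occurred 3545, 3563, 2158, 3490, 1618 and 1917 times, and 51.8% to 58.7% of the values from 1 to 20 in a library were even. Over the 488 genes within that range in every library, 33.6% to 47.5% were even. In 67 rows the count was the same in all 9 libraries and above 0, and the cause was not tested. Whether both reads of a pair were counted was not given in the sources used here, and these values do not settle it, so the limit of 3 counts and the minimum of 10 counts for a present gene may stand for fewer molecules. A minimum of 20 counts was added after the data were seen. Replicates of a group differed far more than counting noise: the chi-square statistic per gene between replicate pairs, which would be about 1 for repeat sequencing of a library, was 62.7 at the lowest, so no library was counted as a duplicate.

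Counts were tested with edgeR 4.0.16 (R 4.3.3). Genes were kept by filterByExpr (17584 of 22637, holding 99.97% to 99.99% of the counts of each library), libraries were scaled by TMM, and a quasi-likelihood model with robust estimation was fitted to all 9 libraries with group as the only term, so that the groups shared 1 estimate of the spread. The pairwise comparisons and a joint test of all 3 groups were two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Standard errors of log2 folds were derived from the F statistic. CPM values are TMM-scaled, and log2 CPM values used a prior count of 2.

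The test was checked on simulated counts drawn with the means, library sizes and dispersions of the real libraries, for 17584 genes. With known changes placed in the CKD group, the CKD against control test recovered 40 of 100 genes changed 2-fold and 74 of 100 changed 4-fold, with 2 unchanged genes among 116 calls. With changes placed in the MSC group, the MSC against CKD test recovered 37 of 100 and 71 of 100, with 9 unchanged genes among 117 calls.

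Whether the replicate numbers of the titles pair the libraries stays open. Of 9 same-numbered pairs across groups, 3 had a correlation of deviations from the group means above 0.1. The values ran from -0.10 to 0.27, against -0.30 to 0.30 in other pairs. Of 9 libraries, 6 correlated best with a library of their own number, but some would do so by chance and a pair can count for both its libraries. The highest correlation, 0.298, joined CKD replicate 2 and MSC replicate 1, of unlike number. The labels name no pairing. The model without a block was kept. Alternatives fixed before the data were examined were other scalings (DESeq2 1.42.0 size factors, upper-quartile, library size only), no filter and a stricter one, DESeq2, limma 3.58.1 voom with sample weights, non-robust estimation, a replicate block, leaving out each library, using only both groups compared, and other thresholds. Adjusted p-values that DESeq2 set to missing were not counted as calls. Thinning of all libraries to 47633344 counts, leaving out the 50 most abundant genes, and the position of each library between control and MSC kidneys were added after the data were seen. That position was computed over genes called in MSC against control without the CKD libraries, as the projection of log2 CPM on the difference between the group means, with 0 at the control mean and 1 at the MSC mean. Control and MSC libraries were placed on an axis made without them. For the planned measure of change from CKD to MSC, genes were called in CKD against control without 1 CKD library and measured against that library, with the sign set by the direction of the call. A negative value is a move towards control only where the left-out library lay on the same side of the controls as the call. Genes were called in a fit that also held the MSC libraries and in one of controls and CKD libraries alone. The version with the CKD libraries in both steps had no value, because edgeR called no gene in CKD against control. The covariance of fold changes planned beside it is given over all tested genes, with its value in 25 simulations of unchanged groups and the value expected from the spread of the shared libraries.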

Results

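Gene expression was measured by RNA sequencing in 9 rat kidneys, 3 controls, 3 from a model of chronic kidney disease (CKD) and 3 treated with mesenchymal stem cells (MSC). The series title places the treatment in a CKD rat model. Genes are known here only by Ensembl identifiers, so changes are described by number, size and level of genes and not by function. Library totals ran from 53059872 to 54234681 counts in control kidneys, from 56442995 to 58546847 in CKD kidneys and from 47633344 to 48767298 in MSC kidneys (n = 3 each). The totals of the 3 groups did not overlap. Genes with at least 1 count numbered 18787 ± 238 in control, 19054 ± 359 in CKD and 19510 ± 44 in MSC libraries, although the MSC libraries were the shallowest. The 10 most abundant genes held 11.8% ± 0.857 of counts in CKD and 16.5% ± 1.48 in MSC kidneys (SD, n = 3 each), and 12.2% to 14.2% in the control libraries.

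The first principal component of log2 CPM values held 56.9% of the variance and set the MSC kidneys apart from the other groups. MSC scores were 118, 100.4 and 66.8, control scores lay between -77.2 and -45.8, and CKD replicates 1 and 3 scored -39.9 and -71.6. CKD replicate 2 stood apart from its group with a score of 9.32. Across genes, Spearman correlations between control and CKD libraries (0.970 to 0.988) had a median of 0.985, against 0.986 between controls and 0.982 between CKD libraries, whereas those between control and MSC libraries ran from 0.915 to 0.965. Genes are not independent replicates, so these coefficients describe the libraries. Jointly, 4601 of 17584 genes (26.2%) differed among the 3 groups by edgeR's quasi-likelihood test at an adjusted p under 0.05. That number was 1795 without MSC replicate 1 and 1478 without MSC replicate 2.

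**Figure D1:**
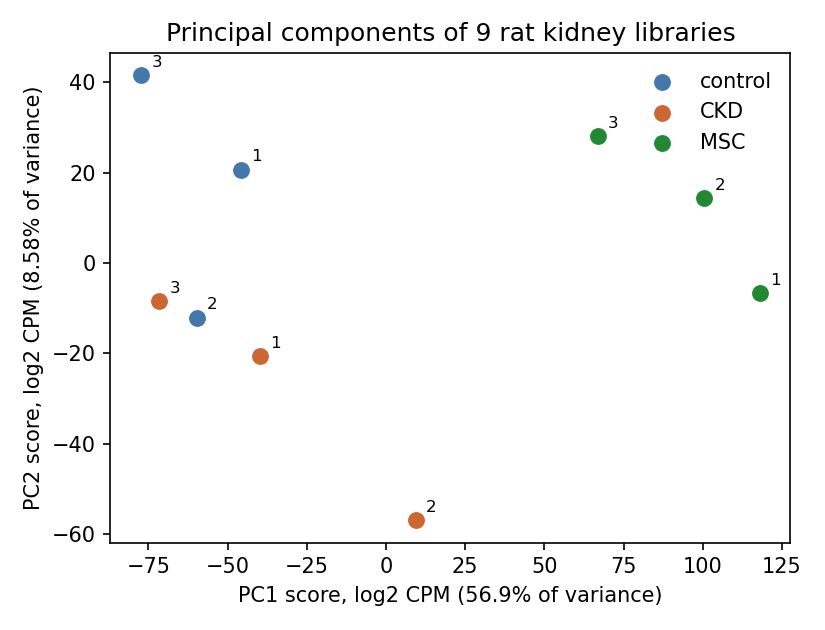
First and second principal components of log2 CPM values over 17584 genes (56.9% and 8.58% of the variance), with 1 point per library labelled by its replicate number and coloured by group. The MSC kidneys lie at scores of 66.8 and above on the first component, CKD replicate 2 lies at 9.32 and all other libraries lie at -39.9 or below.

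The CKD and control kidneys were compared to ask what the disease model changed. No gene differed between them by edgeR's quasi-likelihood test (0 of 17584, smallest adjusted p = 0.207). Before adjustment 1151 genes (6.55%) had p under 0.05, against 879 expected by chance, and 11.8% of genes had no overlap between the 3 CKD and 3 control values, against 10% by chance. limma-voom also called 0 genes, whereas DESeq2 called 71, of which 43 were higher and 28 lower in CKD kidneys. The 95% interval of the fold lay within 2-fold either way for 11193 of 17505 genes (63.9%), and the median interval reached 0.51 on either side on the log2 scale. Intervals used the SE derived from the F statistic, and 79 genes with folds near 0 had none. At 0 counts in all 3 controls and at least 10 counts in each CKD kidney were 9 genes, and no gene showed the opposite. At a minimum of 20 counts the 9 genes became 2. Without CKD replicate 2, the library apart from its group, the count stayed 0. It was 2 without control replicate 1, 1 without CKD replicate 1 and 1 without CKD replicate 3.

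MSC and CKD kidneys were compared to ask what accompanied the treatment. Expression differed in 4010 of 17584 genes (22.8%), 2004 higher and 2006 lower in MSC kidneys (edgeR quasi-likelihood test, adjusted p under 0.05). The median absolute log2 fold of these genes was 0.90. Large changes were mostly increases: 1231 genes were at least 2-fold higher against 556 at least 2-fold lower, and 237 at least 8-fold higher against 39 at least 8-fold lower. Among the 5862 genes with the lowest mean level, 77.4% of 915 called genes were higher in MSC kidneys, while among the 5861 with the highest mean level 33.3% of 1642 were higher. That mean holds the MSC values themselves, so the split in part sets this contrast. With the level taken as the mean of both groups' means, a split added after the data were seen, the shares were 73.5% and 36.1%, and a gene near 0 in CKD kidneys can still be called only in the higher direction. A group of 58 genes had 0 counts in all CKD kidneys and at least 10 in every MSC kidney, and 5 genes showed the opposite. At a minimum of 20 counts these numbers were 17 and 3.

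The called genes also took different parts of the transcriptome. Genes called higher in MSC than in CKD kidneys held 13.1% ± 1.57 of all counts in MSC kidneys, 6.61% ± 1.05 in CKD and 6.34% ± 0.39 in control kidneys (SD, n = 3 each). Genes called lower held 10.8% ± 0.812 in MSC kidneys, 19.2% ± 1.27 in CKD and 18.8% ± 0.605 in control kidneys. These sets were chosen on the same libraries, so the shares for MSC and CKD describe the calls and do not test them. Shares for MSC against control are no test either, since the MSC libraries took part in the choice. MSC and CKD values did not overlap in 43.3% of all tested genes, against 10% by chance. The count of called genes was 1776 without CKD replicate 1, 1641 without CKD replicate 3, 1961 without MSC replicate 1 and 1499 without MSC replicate 2. Leaving out CKD replicate 2 gave 4652.

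**Figure D2:**
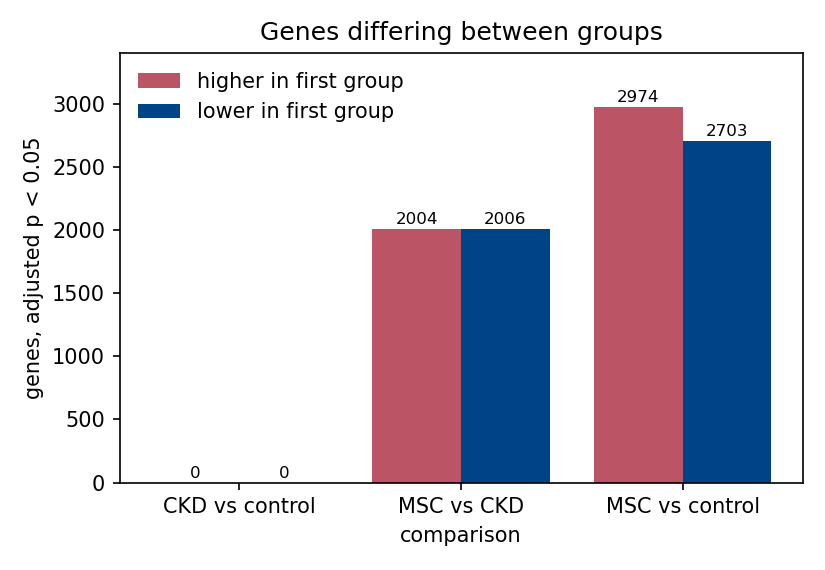
Number of genes with an adjusted p under 0.05 (edgeR quasi-likelihood test, 17584 genes tested) in each comparison, with bars for genes higher and lower in the group named first. CKD against control gave 0 genes, MSC against CKD 2004 higher and 2006 lower, and MSC against control 2974 higher and 2703 lower.

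ENSRNOG00000047915 and ENSRNOG00000030812 had the largest increases by the naming rule, and ENSRNOG00000025757 and ENSRNOG00000016983 the largest decreases. ENSRNOG00000030812 averaged 8.75 ± 4.51 CPM in MSC kidneys, 0.196 ± 0.0494 in CKD and 0.125 ± 0.186 in control kidneys (SD, n = 3 each). Its log2 fold between MSC and CKD was 5.47 ± 0.89 (SE, edgeR adjusted p = 0.00669). ENSRNOG00000047915 had a log2 fold of 6.72 ± 1.62 (edgeR adjusted p = 0.0218), but its MSC values were uneven, at 2.67, 18.9 and 0.84 CPM. Without MSC replicate 2 its log2 fold was 4.62 (edgeR adjusted p = 0.109) and without CKD replicate 3 it was 6.16 (edgeR adjusted p = 0.0698), in a range of 4.62 to 8.61 without single libraries. With limma-voom the fold was 7.00. Over the alternatives run for this gene the adjusted p ran from 0.0102 with DESeq2 to 0.228 with limma-voom. ENSRNOG00000025757 averaged 9.29 ± 0.955 CPM in CKD kidneys and ranged from 5.63 to 15.4 CPM in controls. In MSC kidneys it had 6, 0 and 0 counts, and its log2 fold against CKD was -7.77 ± 0.80 (SE, edgeR adjusted p = 0.00225). That size depends on edgeR's own handling of 0 counts and on 1 library, because 2 of its 3 MSC libraries had no count. The prior count of 2 was used for log2 CPM values and not for this fold. The fold was -11.96 without MSC replicate 1, the library with counts, and -9.34 with limma-voom. Its SE, derived from the F statistic, does not cover these shifts. ENSRNOG00000016983 averaged 5.07 ± 0.527 CPM in CKD, 6.08 ± 2.48 in control and 0.119 ± 0.117 in MSC kidneys, with a log2 fold of -5.37 ± 0.72 between MSC and CKD (edgeR adjusted p = 0.0038). That fold was -6.30 without MSC replicate 1 and -4.81 without MSC replicate 2, the library with 0 counts, and -7.72 with limma-voom. Between CKD and control kidneys the log2 folds of the 4 genes were 0.06 ± 1.86, 0.61 ± 0.94, -0.37 ± 0.51 and -0.26 ± 0.55 in the order named, none past the threshold (edgeR adjusted p of 0.895 or more).

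**Figure D3:**
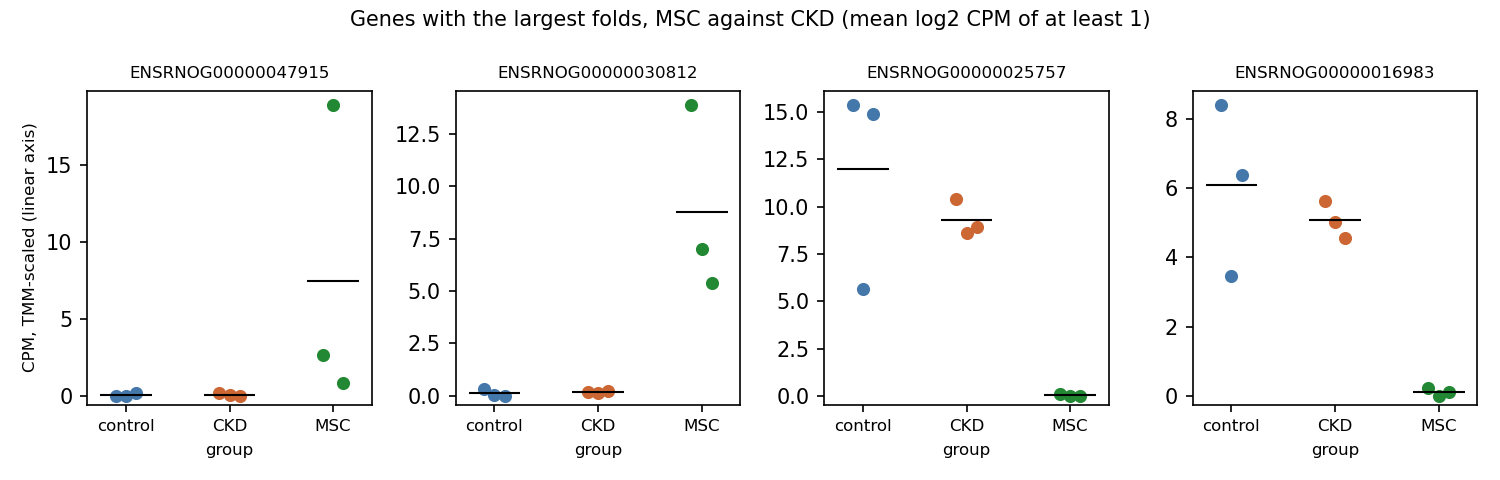
CPM values (TMM-scaled, linear axes) of ENSRNOG00000047915, ENSRNOG00000030812, ENSRNOG00000025757 and ENSRNOG00000016983 in each library, with points for libraries and lines for group means. In MSC kidneys ENSRNOG00000047915 reached 18.9 CPM in replicate 2 and 0.84 in replicate 3, and ENSRNOG00000025757 was at 0.117 CPM or below.

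MSC and control kidneys were compared to ask how far treated kidneys lay from controls. This comparison had the most genes, with 5677 of 17584 (32.3%) called, 2974 higher and 2703 lower in MSC kidneys (edgeR quasi-likelihood test, adjusted p under 0.05). Again the larger changes were mostly increases, with 2017 genes at least 2-fold higher and 766 at least 2-fold lower. Among the genes with the lowest mean level 79.8% of 1483 called genes were higher, and among those with the highest level 32.8% of 2211 were, a contrast with the same limits. With the level taken from both groups' means the shares were 78.1% and 34.5%. All 3 controls had 0 counts and every MSC kidney at least 10 counts for 105 genes, and 7 genes showed the opposite. At a minimum of 20 counts these numbers were 41 and 5. The count was 3232 without control replicate 3, fewer than the 3704 genes then called between MSC and CKD. It was 3261 without MSC replicate 1 and 3077 without MSC replicate 2.

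Most genes that differed between MSC and CKD also differed between MSC and control. In the same direction in both were 1669 higher and 1677 lower genes, or 83.4% of the genes called against CKD, and 1 gene was called in opposite directions. Independent lists of these sizes would share 339 higher and 308 lower genes, and the simulated unchanged groups called at most 1 gene in either comparison, so they give no useful chance value for shared calls. The MSC libraries serve in both comparisons and 3 libraries cannot be split into sets of at least 2, so part of the excess may come from the shared libraries. The covariance of the log2 folds across genes was 1.08, against 0.103 in simulated unchanged groups.

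The direction of change from CKD to MSC was set against that from control to CKD, to ask whether treated kidneys moved back towards the controls. Sharing the CKD libraries alone gives a negative covariance between both sets of log2 folds: -0.101 in the simulations and -0.127 from the spread of the CKD libraries. The observed covariance was 0.041, which lay 0.168 above the latter value. A positive difference means that folds from CKD to MSC tended to run in the same direction as those from control to CKD. Without single libraries the difference was lowest, at 0.0401, without CKD replicate 2 and highest, at 0.235, without CKD replicate 3. It therefore depends on CKD replicate 2, the library apart from its group. The planned measure on called genes rested on single genes. With the MSC libraries in the fit, 1 gene was called without CKD replicate 1, 0 without CKD replicate 2 and 1 without CKD replicate 3. Signed by the call, CKD replicate 1 lay at -0.33 from the control mean on the log2 scale for its gene and the MSC mean a further -0.28 from it. CKD replicate 3 lay at 0.23 from the control mean for its gene and the MSC mean a further 0.21 from it. With controls and CKD libraries alone in the fit the counts were 0, 0 and 1, and for the last gene these values were 1.56 and 5.25. None of these changes was tested.

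Over the 5645 genes called between MSC and control without the CKD libraries, each CKD library was placed between the control mean (0) and the MSC mean (1). Each control and MSC library was placed on an axis made again without it, so the positions compared rest on different axes. This measure was chosen after the data were seen. CKD replicates 1, 2 and 3 lay at 0.179, 0.466 and -0.00594, a mean of 0.213 ± 0.238 (SD, n = 3). Held-out controls lay at 0.0932 ± 0.109 and held-out MSC kidneys at 0.941 ± 0.225. A two-sided exact permutation test gave p = 0.6 for CKD against control positions and p = 0.1 for MSC against CKD (n = 3 each), and 0.1 is the smallest p this design allows, so neither comparison could pass the threshold. In CKD replicate 2, 71.0% of these genes lay beyond all 3 controls on the MSC side, against 25% by chance, although these genes were chosen with the same controls, which favours that side. The shares were 34.4% in CKD replicate 1 and 26.1% in CKD replicate 3.

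**Figure D4:**
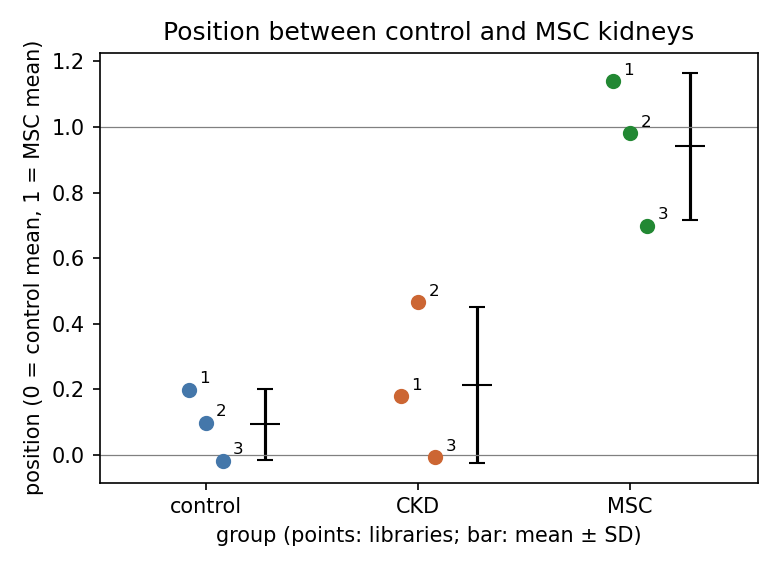
Position of each library between the control mean (0) and the MSC mean (1) over genes called between those groups, with numbered points for libraries and bars for the mean ± SD of each group. Each control and MSC point comes from an axis made without that library. CKD replicate 2 lies at 0.466, between the controls (0.199 or lower) and the MSC kidneys (0.699 or higher).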

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

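The numbers of called genes kept within 1.5 times of the values reported under most alternatives, and all genes called in MSC against CKD or against control kept their sign wherever they were tested. Exceptions came from the tool, a fold minimum and single libraries. DESeq2 called 71 genes in CKD against control instead of 0, and limma-voom with sample weights called 6907 genes in MSC against CKD and 7402 among the 3 groups. The cause was not tested. A minimum of 2-fold by construction left 1787 genes in MSC against CKD and 2783 in MSC against control. Within 1.5 times, a fit of only the 6 MSC and CKD libraries called 2858 genes and kept 2738 of the 4010 calls. Only the 6 MSC and control libraries gave 5645 genes. Without each library in turn, which leaves fewer samples, the count ran from 0 to 2 in CKD against control, from 1499 (without MSC replicate 2) to 4652 (without CKD replicate 2) in MSC against CKD, from 3077 to 5890 in MSC against control and from 1478 to 5103 among the 3 groups. MSC against CKD fell to 1776, 1641 and 1961 without CKD replicate 1, CKD replicate 3 and MSC replicate 1, and MSC against control to 3232 and 3261 without control replicate 3 and MSC replicate 1. Among the 3 groups it fell to 1795 without MSC replicate 1. The position of the CKD group ran from 0.086 to 0.322, and the covariance beyond the shared libraries from 0.0401 (without CKD replicate 2) to 0.235 (without CKD replicate 3). A fit with the replicate block gave 0, 4493, 6033 and 4928 genes in the 3 comparisons and the joint test and ended no call of the 4 named genes. The labels do not say that the numbers pair the libraries. That 6 of 9 libraries correlated best with a library of their own number is a weak hint, since some would do so by chance. It comes from the data and not from the design. The fold of ENSRNOG00000047915 between CKD and control, never past the threshold, was -0.17 with the replicate block and ran from -1.83 to 4.94 without single libraries, being -0.50 without control replicate 1 and -0.53 without control replicate 2. That of ENSRNOG00000016983 ran from -0.54 to 0.060 (without control replicate 1), that of ENSRNOG00000030812 from 0.065 (without control replicate 3) to 3.197 (without control replicate 1) and that of ENSRNOG00000025757 from -0.70 (without control replicate 2) to -0.12 (without control replicate 1). Scaling moved the median log2 fold of all genes by less than 0.1 in every comparison. The balance of directions also changed with scaling, not always in the direction of that median: with library size only, 1516 genes were higher and 1664 lower in MSC against CKD and 2916 and 1973 in MSC against control, and with upper-quartile factors 2098 and 1773, and 3164 and 2328. The gene list tests were not run, since no identifier had a name. The planned change from CKD to MSC in called genes was run only with each CKD library left out, where it rested on 1 gene at most, and its other alternatives were not run. Depth limits what can be said of genes with few counts, and thinning every library to the smallest total left 4046 genes in MSC against CKD.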

Other observations

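The splits of the samples were planned before the data were examined. The tests of depth, abundant genes, exchanged labels and mixing were chosen after the main counts of genes and the principal components had been seen. The comparison with libraries midway on the log scale and the test on genes near 0 were added after the first mixing result had been seen. The 58 genes at 0 counts in every CKD kidney and with at least 10 counts in every MSC kidney, and the 105 at 0 in every control, form sets that could be looked up with gene names. At a minimum of 20 counts they held 17 and 41 genes. The genes lower in MSC than in CKD kidneys held 10.8% of all counts in MSC kidneys against 18.8% in controls. They were chosen with the same MSC libraries, which favours a lower share there, so these shares are no test.

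The first pattern is that MSC kidneys differed from both other groups while no gene was called between CKD kidneys and controls by edgeR. Fewer counts in the MSC libraries were argued against as the whole cause, since 4046 genes were called between MSC and CKD with all libraries thinned to the smallest total, against 4010. A few abundant genes were argued against too as the whole cause, since leaving out the 50 most abundant left 3992. Both fits used TMM scaling, which already limits such an effect, so little change could follow. With library size only, 3180 genes were called between MSC and CKD. What stays open is a cause shared by a whole group: library totals did not overlap between groups and the labels give no batch, so batch and group cannot be told apart. An exchange of the CKD and MSC labels as whole groups also cannot be told apart from a response to the cells or the infusion, since 0 identifiers had a name and no gene known to change in kidney disease could be looked up.

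The second pattern is the place of CKD replicate 2, at 0.466 between controls and MSC kidneys. Its depth was argued against, since its position was 0.467 after thinning, and so was an exchange of 1 CKD and 1 MSC library, since the lowest held-out MSC position was 0.699. Mixing with RNA of an MSC kidney stays open. The share computed from genes lower in MSC minus that from genes higher in MSC averaged -0.101 over 3 references, each without 1 MSC library. Libraries midway on the log scale gave 0.214 to 0.391. The 6 mixtures made from real libraries (-0.207 to 0.142) depended on the MSC library mixed in, and none lay near that mean. Without MSC replicate 1 the value was -0.173, and mixtures with that library gave -0.207 and -0.161. Without MSC replicates 2 and 3 the values were -0.0724 and -0.0573, below the mixtures with those libraries (0.0814 to 0.142). All mixtures were made at a share of 0.413, and at that share the difference matched those with MSC replicate 1 only. The shares behind it did not match. From genes higher and lower in MSC they were 0.561 and 0.388 in CKD replicate 2 without MSC replicate 1. The mixtures with MSC replicate 1 gave 0.781 and 0.574, and 0.684 and 0.523. Other shares were not run, so the difference does not name a library. A second test used genes near 0 in controls and CKD replicates 1 and 3. At 4 of 9 cutoffs more of them lay far below the level that the mixing share would give in CKD replicate 2 than in the mixtures, which goes against mixing. At the other 5 they did not, and some ran the opposite way: 30%, 33.3% and 44.4% in CKD replicate 2 against 60%, 66.7% and 66.7% in the mixtures. The result depends on the cutoff and on few genes near the floor. Summed over the 3 references they numbered 6 to 118, and 1 gene can be counted under each reference. A kidney sample holding affected and unaffected tissue may give the same values, and a difference in disease between animals was not tested.

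Other splits of the samples were counted for each comparison. Among the 3 groups 4601 genes were called, and 2 of 100 splits of the 9 libraries, the real one included, gave as many, a share under 0.05. That argues against a random grouping of the 9 libraries and does not bear on the parting of CKD from control kidneys. The highest other split gave 5033 genes. The 5 other splits that kept the MSC kidneys together gave 3865 to 5033 genes and the 94 that parted them at most 1, which points to a structure of MSC kidneys against the rest. For the pairs of groups, 10 splits are too few for a share under 0.05. The real split gave 4010 genes between MSC and CKD (1 of 10 splits as large, highest other 0), 5677 between MSC and control (1 of 10, highest other 0) and 0 between CKD and control (10 of 10, highest other 2).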
